A study of Thermus thermophilus HB27 with 8 samples.

How the data were processed

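The series measured where the DEAD-box protein Hera contacts RNA in the thermophilic bacterium Thermus thermophilus HB27. The assay was eCLIP, in which UV light cross-links a protein to the RNA it touches and the protein is then precipitated with its RNA fragments. Per the labels' protocols, cells grew at 75 °C and were either cross-linked directly (normal growth) or first kept at 60 °C for 10 min (cold shock). Complexes between 55 and 130 kDa were cut from the membrane. Of the 8 samples, 4 are eCLIP libraries (2 per condition, from separate cultures) and 4 are size-matched inputs, which hold the RNA of the same size range without precipitation. The labels give cultures harvested at an optical density of 0.8 and of 1.0 in each condition, and the sample titles do not say which replicate had which density. If the libraries follow the order in which the labels number the cultures, normal growth replicate 1 and cold shock replicate 2 were at 1.0 and the others at 0.8.

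Each eCLIP library came as 1 peak list with no header, so the authors called peaks per library and not on pooled replicates. The input samples had no list of their own here and enter only through the normalisation of the peaks. Each list gives position, strand, the deposited −log10 p-value of eCLIP against input reads, the deposited log2 fold over input, and a deposited score. Per the submitters' processing notes, cutadapt, STAR and SAMtools were used, and their versions, the peak caller and the genome build are not given in the sources used here. Sequence names in the lists are those of the RefSeq HB27 chromosome and of a second, smaller replicon. All coordinates below are those of the lists, written 1-based.

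The fold and p of a peak are the authors' values and were used to describe, rank or filter peaks within a list. The fold was also set side by side between conditions at regions, without a test of the difference. The score equalled the share of a library's eCLIP reads in the peak times the log2 ratio of that share to the share of input reads. Solving score and log2 fold together gave eCLIP and input reads per peak that were whole, within 0.02 reads, in 99.9% to 100.0% of peaks. The deposited p equalled Fisher's exact test or the chi-square test with Yates' correction on those reads, within 1% of −log10 p, in 100% of 1000 peaks drawn at random per library among those with a fold above 1 and a −log10 p below 300. These implied library totals were 1348154 and 1582167 eCLIP reads for normal growth replicates 1 and 2, and 1047431 and 1183571 for cold shock replicates 1 and 2. The inputs held 4932621, 4677910, 5918140 and 4735132 reads in the same order. The deposited −log10 p-values are 0 where the fold is below 1 and reach at most 400. A peak without input reads carries 1 input read, so 0 and 1 cannot be told apart and the fold of such a peak depends on that floor. The fewest eCLIP reads in a peak was 3. With 1 input read, a peak passed the limits below from 5 to 7 eCLIP reads, depending on the library. Reads can span neighbouring peaks, so reads were never summed over peaks.

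An enriched peak had a log2 fold of at least 3 (at least 8-fold) and a −log10 p of at least 3. Peaks were compared by overlap of at least 1 nt on the same strand. Mean overlap is the average of both directions, set beside 100 random shifts of 1 list along each replicon. Peaks of all 4 lists that overlapped or touched on a strand were merged into regions, and a region was bound in a library that had an enriched peak there. Agreement between libraries was tested with two-sided Fisher's exact tests over regions with a deposited peak in both, with Benjamini-Hochberg adjustment over 6 pairs. The share of enriched peaks on the second replicon and on each strand was tested against other peaks of the same list in the same way, adjusted over 12 tests. Conditions were compared with exact permutation tests of 2 libraries against 2, which have 3 splits and a smallest two-sided p of 0.333. Read numbers were compared as RPM, that is, reads scaled to the total of the library, at the peak with the most eCLIP reads of each region, over the regions with a peak in all 4 lists. That main peak was chosen in each library separately, so its position and width in the region can differ between libraries. Part of a difference between libraries can come from this choice. A region differed between conditions when both libraries of one lay more than 2-fold above both of the other, and input changes also needed at least 10 input reads in both higher libraries. This comparison of reads was added after the data were seen. No count model was fitted, since peak reads are only implied by deposited ratios. Reads are not independent molecules, so intervals cover counting error only.

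The gene-level results planned before the data were examined (RNA class, tRNA genes, gene lists, position along genes, GC content, and named genes) were not run. The table of genes used here is that of another strain, HB8, whose coordinates differ, and no genome sequence was used here. Regions took the place of genes, and replicon and strand took the place of RNA class. The planned rule for naming genes was applied to regions. Per condition it takes the 12 regions bound in both libraries with the highest lower value of their best log2 fold, and the 5 such regions bound in that condition only. Alternatives fixed before the data were examined were stricter limits (log2 fold 4, −log10 p 5), a looser fold limit (log2 fold 2), a 50% overlap, merging of enriched peaks, leaving out each library, pairing by replicate number, and, for regions bound in 1 condition only, the looser fold limit in the other condition. Where enriched peaks were merged to compare replicons and strands, the other peaks were merged as well. Further alternatives were chosen after the data were seen and are named as such in the closing section.

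The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calculations were tested on simulated data. Reads came back from simulated folds and scores in 99.9% to 100.0% of peaks per library. Overlaps equalled those of bedtools 2.31.1 for 100% of 3000 simulated intervals. Among 1254 simulated regions with counting error only, the rule for eCLIP reads called 90.0% of 200 regions lowered 4-fold in cold shock and 99.5% of 200 lowered 8-fold, with 1 and 0 unchanged regions called. The rule for input reads called 80.4% of the 56 regions raised 4-fold that had enough reads, and 78.8% of 151 raised 8-fold, with 0 unchanged regions called. In these simulations all libraries had the same RPM at an unchanged region. Outside the 4 loci described below, median eCLIP RPM was 33.4 and 17.1 in normal growth replicates 1 and 2. In cold shock replicates 1 and 2 it was 16.2 and 32.1. The simulated rates for eCLIP reads therefore do not carry over to the real libraries.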

Results

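RNA contacts of Hera, a DEAD-box RNA helicase, were mapped by eCLIP in Thermus thermophilus HB27 during normal growth at 75 °C and after 10 min at 60 °C. Each condition had 2 eCLIP libraries, and each peak was normalised to a size-matched input. The lists held 8327 and 8059 peaks for normal growth replicates 1 and 2, and 6900 and 5970 peaks for cold shock replicates 1 and 2. The implied depth ranged from 1047431 to 1582167 eCLIP reads and from 4677910 to 5918140 input reads per library.

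Where Hera contacts RNA was asked first in each library on its own. Enriched peaks, at least 8-fold over input, lay on both strands of both replicons in every library. Normal growth replicates 1 and 2 had 7129 and 5939 enriched peaks, which were 85.6% and 73.7% of their lists. Cold shock replicates 1 and 2 had 5259 and 4940, or 76.2% and 82.7%. Enriched peaks were short, with a median length of 32 nt in both normal growth libraries and of 30 and 37 nt in cold shock replicates 1 and 2. Their median log2 fold was 5.96, 5.37, 5.31 and 5.81 in the same order. Between 48.5% and 82.7% of them had a single input read, the lowest value in the lists, so the folds of those peaks rest on that floor.

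After merging, the 4 lists covered 14304 regions, of which 11927 were bound in at least 1 library. Only 1093 regions (9.16%) were bound in all 4 libraries, and 6663 (55.9%) were bound in exactly 1. The regions bound in all 4 libraries had a median length of 89 nt, against 34 nt for all regions. Regions join overlapping peaks of all lists, so regions with peaks in more lists are longer by the merging itself. The 1254 regions with a peak in all 4 lists, bound or not, had a median of 87 nt. The regions bound in all 4 libraries were spread widely, with 778 of 4256 windows of 1000 nt and 1 strand holding at least 1 of them. The densest window, at 1654001 to 1655000 on the plus strand of the chromosome, held 5.

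How well replicates repeated each other was compared with pairs across conditions. Normal growth replicates shared 49.3% of their enriched peaks on average and cold shock replicates 34.8%. Random shifts gave 10.4% and 8.46% for these pairs. The highest overlap of the 6 pairs, 54.1%, was that of normal growth replicate 1 with cold shock replicate 2, so overlap did not follow condition. Among the 1000 enriched peaks with the highest −log10 p of each library, the normal growth pair overlapped most, at 63.95%, followed by normal growth replicate 1 with cold shock replicate 2, at 57.05%. The cold shock pair overlapped least in both sets, with 31.5% among the strongest peaks. Requiring a 50% overlap of both peaks lowered the shares to 27.5% for normal growth and 16.4% for cold shock.

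**Figure D1:**
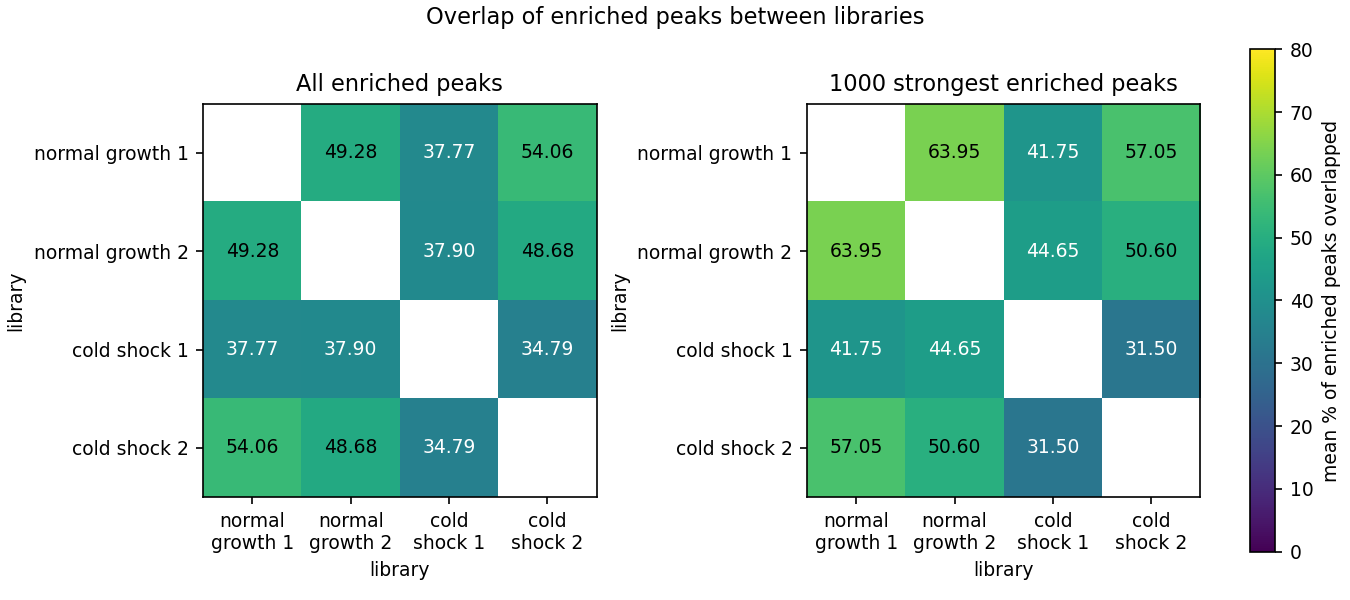
Mean share of enriched peaks (%) of each pair of libraries that overlap by at least 1 nt, for all enriched peaks (left) and for the 1000 with the highest −log10 p of each library (right); rows and columns are the 4 eCLIP libraries. Normal growth 1 and cold shock 2 overlap most on the left (54.1%), the normal growth pair on the right (63.95%), and the cold shock pair least on both sides.

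Where both libraries of a pair had a deposited peak, they mostly gave the same call. Of 3205 such regions of the normal growth pair, 2817 were bound in both and 135 in neither (odds ratio 56.8, two-sided Fisher's exact test, adjusted p = 2.66e-108). Of 2023 regions of the cold shock pair, 1758 were bound in both and 115 in neither (odds ratio 50.2, two-sided Fisher's exact test, adjusted p = 2.00e-89). With stricter limits the odds ratios were 27.6 for normal growth and 11.0 for cold shock, and at equal depth, where their order turned, 26.3 and 31.2. The odds ratio was highest, at 137, for normal growth replicate 1 with cold shock replicate 2, and lay between 19.3 and 32.1 for the other 3 pairs across conditions. The 66 regions in the 4 loci of depleted peaks described below had a peak in every list and no enriched peak. They count as bound in neither in every pair and so raise all these odds ratios. Regions are not independent replicates, so these p-values describe these libraries only.

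The regions with the highest enrichment in normal growth lay mostly on the chromosome and were mostly bound in cold shock too. The first, at 340854 to 340965 on the plus strand of the chromosome, had 281 and 183 eCLIP reads in replicates 1 and 2 against 4 and 1 input reads at its main peak. The best log2 fold of any peak in the region was 9.80 and 9.08, and it was also bound in cold shock, at 6.42 and 8.71. It was 1 of 4 regions of the top 12 that lay between 340393 and 341367 on that strand. The second had a best log2 fold of 10.01 and 9.02 in normal growth, at 340393 to 340477, with 352 and 175 eCLIP reads against 4 and 1 input reads at its main peak. The third, at 438370 to 438465 on the minus strand, had log2 folds of 9.54 and 8.92 in normal growth, each against 1 input read, and 5.96 and 5.55 in cold shock. All 12 had a lower log2 fold of at least 8.10, 9 of them were bound in all 4 libraries, and 11 lay on the chromosome.

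In cold shock the top 12 regions had lower log2 folds between 7.36 and 7.82, and all 12 were also bound in both normal growth libraries. The first, at 101824 to 102169 on the plus strand of the second replicon, had 40 and 151 eCLIP reads in cold shock replicates 1 and 2 and 154 and 104 in normal growth, always against 1 input read. Its log2 folds were 7.82 and 9.24 in cold shock and 9.14 and 8.26 in normal growth. At 1080926 to 1080986 on the minus strand of the chromosome, log2 folds were 8.84 and 7.59 in cold shock and 7.36 and 6.77 in normal growth. Of the 12 regions, 8 lay on the chromosome. The top lists of the conditions shared 2 regions, the one at 101824 on the second replicon and one at 341288 to 341367 on the plus strand of the chromosome.

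Whether cold shock changed the set of bound regions was asked next. Both normal growth libraries bound 2817 regions and both cold shock libraries 1758, of which the 1093 shared ones were 38.8% and 62.2%. Bound in normal growth only were 585 regions, and in cold shock only 207. Their sum of 792 lay between those of the other ways to split the libraries into pairs. Grouping libraries by replicate number gave 756 regions bound in 1 pair only, and grouping normal growth replicate 1 with cold shock replicate 2 gave 1026. An exact permutation test over these 3 splits cannot give a p below 0.333. With 1 library left out, the counts ranged from 964 to 2684 for normal growth only and from 380 to 2156 for cold shock only, since fewer libraries then had to pass.

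Of the 5 strongest regions bound in 1 condition only, 5 of normal growth and 4 of cold shock lay on the chromosome. The strongest of normal growth, at 1068353 to 1068380 on the minus strand of the chromosome, had 79 and 68 eCLIP reads against 1 input read each (log2 fold 8.18 and 7.65). The next, at 237806 to 237868 on the plus strand, had 130 and 58 eCLIP reads (7.89 and 7.42). The strongest of cold shock, at 7516 to 7549 on the plus strand of the second replicon, had 22 and 34 eCLIP reads against 1 input read each (6.96 and 7.09). Another, at 591072 to 591126 on the minus strand of the chromosome, had 28 and 22 (7.31 and 6.46). In the other condition none of these 4 regions had a deposited peak. The same was true of 537 of the 585 regions and of 193 of the 207, and a missing peak does not say how many reads were there.

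At the 1254 regions with a peak in every library, few differences in eCLIP RPM between conditions exceeded 2-fold in both libraries of each. Outside the 4 loci of depleted peaks described below, replicates differed in level. The median was 33.4 and 17.1 RPM in normal growth and 16.2 and 32.1 in cold shock. The rule could therefore miss changes, and a low count does not show that few regions changed. Cold shock lay more than 2-fold above normal growth in 1 region and below it in 3, chosen for mention after their values were seen. The 1 higher region, at 1790451 to 1790607 on the plus strand of the chromosome, had 13.4 and 13.5 eCLIP RPM in cold shock against 6.68 and 6.32 in normal growth, from 9 to 16 reads per library. The lower ones lay on the chromosome at 165861 to 165949 and 1630821 to 1631014 on the plus strand and at 1442962 to 1443050 on the minus strand. At 165861 the values were 34.4 and 22.8 in cold shock against 102 and 74.6, at 1630821 they were 73.5 and 71.8 against 217 and 154, and at 1442962 they were 8.59 and 9.29 against 23.0 and 20.2. After centring each library on its median region the counts were 12 higher and 4 lower, so the direction depended on the scaling. In 15.9% of regions the conditions did not overlap, and in 25.04% after centring, against 33.3% by chance if all 4 libraries were exchangeable, which the likeness of normal growth replicate 1 and cold shock replicate 2 speaks against. Within pairs formed across conditions from these 2 libraries and from the other 2, cold shock was more than 2-fold higher in both pairs in 6 regions and lower in 17, and 15 and 12 after centring. Both pairs moved the same way in 46.9% of regions, against 50% by chance. With 1 library left out the counts ranged from 3 to 103 higher and from 6 to 127 lower. Normal growth replicate 1 and cold shock replicate 2 together lay more than 2-fold above the other libraries in 221 regions and below them in 1, and after centring in 16 and 49, so the direction of this split across conditions turned with the scaling too.

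Input RPM, in contrast, was higher after cold shock at a small set of regions. At 18 regions both cold shock inputs lay more than 2-fold above both normal growth inputs with at least 10 reads each. No region met that rule in the other direction or, in either direction, under the other splits of the libraries into pairs (0 regions each). The 18 are not all independent. Input reads at 1537489 (1361, 1245, 15373 and 12383) nearly equalled those at 1891748 (1373, 1256, 15585 and 11103). Those at 1537593 (35, 37, 1197 and 137) nearly equalled those at 1891679 (34, 36, 1202 and 135). The counts, medians and test below take all 18 as separate. The median change at the 18 regions was 3.28 on the log2 scale for input (quartiles 2.92 and 3.38) and 0.09 for eCLIP (quartiles −0.17 and 0.21). By library, the median input change was 4.52 in cold shock replicate 1 and 1.98 in replicate 2. The median eCLIP change was 0.55 in replicate 1 and −0.47 in replicate 2, so eCLIP moved in opposite directions in the replicates. Of the 18 regions, 12 were 41 nt or shorter (66.7%), against 37 of the 85 other regions with at least 10 input reads in both cold shock libraries (43.5%; two-sided Fisher's exact test, p = 0.118, tested after the lengths were seen). The 4 loci of depleted peaks described below, rich in input reads, hold 66 regions with a peak in all 4 lists. Only 2 of those are among the 18, so much of the 85 can come from these loci. The test therefore does not compare the 18 with regions outside the loci. The deposited log2 fold was lower in both cold shock libraries than in both normal growth libraries at all 18, and it was at least 3 in both libraries of normal growth at 16 and of cold shock at 4. This lower fold follows largely from the choice of regions, since the fold is taken over input and eCLIP changed little in the median.

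The examples named here were also chosen after their values were seen. At 1537489 to 1537558 on the plus strand of the chromosome, input held 1361 and 1245 reads in normal growth and 15373 and 12383 in cold shock, while eCLIP held 997, 988, 910 and 842. The log2 fold was 1.33 ± 0.14 in normal growth and −1.73 ± 0.21 in cold shock (SD, n = 2). At 336629 to 336700 on the plus strand, input held 257 and 151 reads in normal growth and 2085 and 641 in cold shock, and the log2 fold was 4.43 ± 0.20 and 1.77 ± 1.08 (SD, n = 2). At 1831791 to 1831822 on the plus strand, input held 10 and 10 reads in normal growth and 321 and 35 in cold shock, and the log2 fold was 6.81 ± 0.35 and 3.60 ± 0.25 (SD, n = 2). Input was higher in cold shock replicate 1 than in replicate 2 at 16 of the 18 regions. The number of such regions was 9 after centring on the median region, whose input is only 1 or 2 reads, and it was 33 without cold shock replicate 1 and 45 without cold shock replicate 2, where fewer libraries had to pass. After centring, the input change of the 18 regions had quartiles of 2.56 and 3.02 on the log2 scale.

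**Figure D2:**
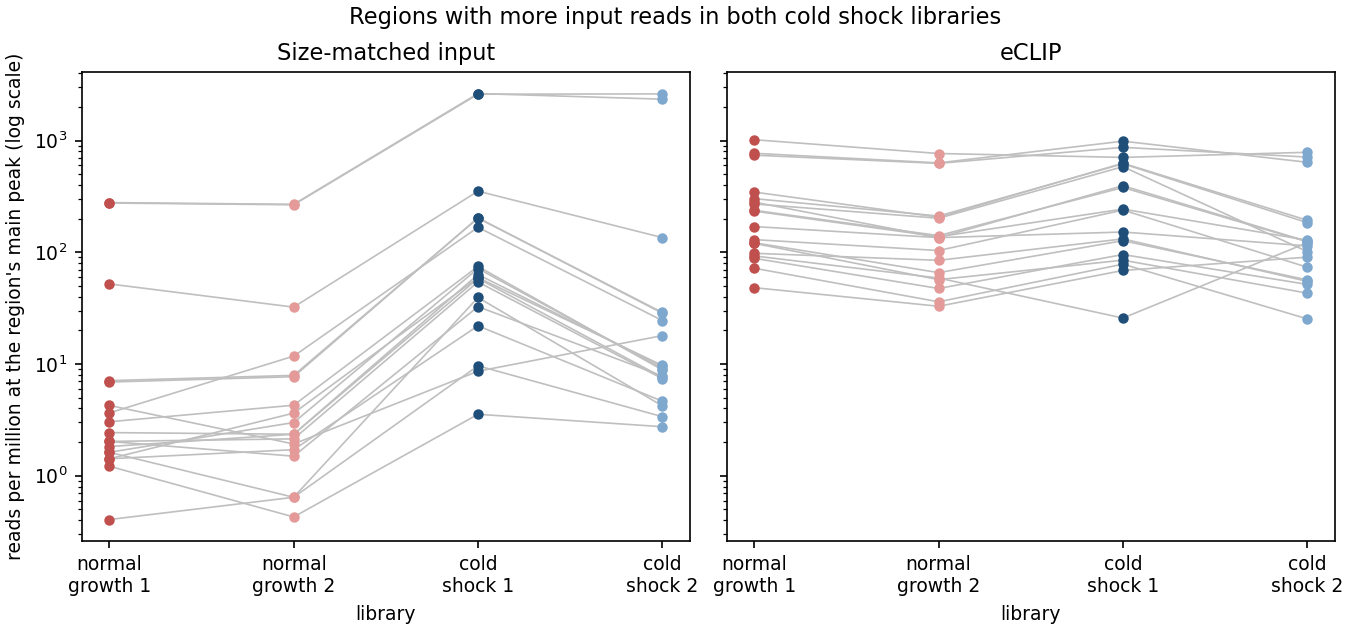
RPM (log scale) at the main peak of the 18 regions with more input reads in both cold shock libraries, in the size-matched input (left) and in eCLIP (right); each line is 1 region and each point 1 library. The median log2 change of input is 4.52 in cold shock 1 and 1.98 in cold shock 2, and that of eCLIP is 0.55 and −0.47.

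A separate question is where Hera libraries held less RNA than input. Depleted peaks, with a fold below 1, numbered 1465, and 98.6% of them lay in 4 loci of the chromosome. Of these, 1 lay on the plus strand, at 1534677 to 1537558. The others lay on the minus strand, at 1891748 to 1894791, at 1765204 to 1766601 and at 1310310 to 1311707. None of the 2309 peaks in the 4 loci was enriched. Peak ends repeated between loci. With peaks up to 200 nt beyond the loci included, 72.4% of 312 peaks at 1765204 had both ends matched by a peak at 1310310 at 1 fixed offset. In mirror image, 31.9% of 886 peaks at 1534677 were matched at 1891748. Of 2267 peaks with at least 1000 input RPM, 2263 lay in these loci. The median log2 fold at 1765204 to 1766601 was −0.94, −0.85, −1.37 and −0.96 in normal growth replicates 1 and 2 and cold shock replicates 1 and 2. At 1534677 to 1537558 it was −0.34, 0.08, 0.19 and −0.24.

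**Figure D3:**
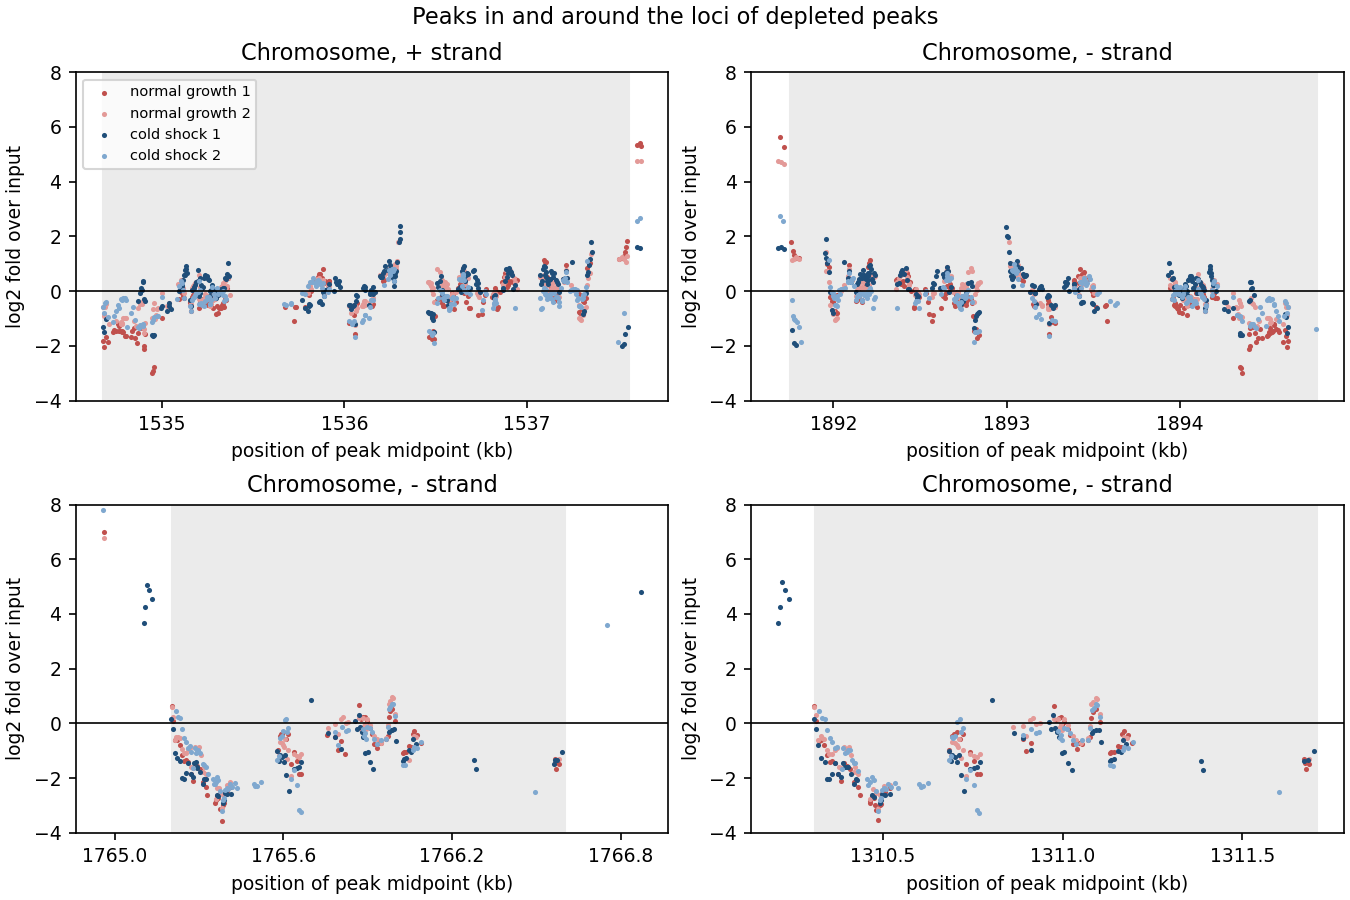
Log2 fold over input of every deposited peak against the position of its midpoint (kb on the chromosome) in and around the 4 loci of depleted peaks, shaded, with points coloured by library. Inside the loci no peak is enriched, and at the right end of the locus at 1534677 and the left end of that at 1891748 the main cold shock peaks lie below 0 (log2 fold −1.58 and −1.88 at 1537489) and those of normal growth above it (1.42 and 1.23).

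Enriched peaks were rarer on the second replicon than other peaks were. It held 5.95% of enriched peaks (95% Wilson interval 5.42 to 6.52) in normal growth replicate 1, 5.22% (4.68 to 5.81) in replicate 2, 5.08% (4.52 to 5.70) in cold shock replicate 1 and 5.49% (4.88 to 6.16) in replicate 2. It held 10.8%, 10.7%, 8.23% and 7.57% of the other peaks. Those other peaks include all 2309 of the 4 depleted loci of the chromosome, which lower the share of the second replicon among them. The odds ratios therefore depend on how finely those loci were cut into peaks. The odds ratios were 0.524, 0.462, 0.597 and 0.708 (two-sided Fisher's exact tests, adjusted p = 3.56e-08, 2.42e-15, 2.14e-05 and 0.0171). With all libraries thinned to equal depth, the odds ratio of cold shock replicate 2 was 0.793 and no longer passed (two-sided Fisher's exact test, adjusted p = 0.113). With touching or overlapping peaks merged first, separately among the enriched and among the other peaks, the odds ratios were lower, at 0.324, 0.368, 0.427 and 0.393. Regions bound in all 4 libraries numbered 55.3 per 100 kb of the chromosome and 19.8 per 100 kb of the second replicon, up to the last peak of each.

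The plus strand of the second replicon held more of its enriched peaks in both cold shock libraries (73.8% and 72.0%) than in both normal growth libraries (67.5% and 69.7%), and the other shares compared differed by less than 1 point. The second replicon held 5.58% ± 0.515 of enriched peaks in normal growth and 5.28% ± 0.289 in cold shock (SD, n = 2, exact permutation p = 0.667). The minus strand held 56.5% ± 1.28 and 56.2% ± 0.373 of the enriched peaks of the chromosome (SD, n = 2, exact permutation p = 1). The plus strand held 68.6% ± 1.57 and 72.9% ± 1.29 of those of the second replicon, a difference of 4.30 points with the smallest p that 2 against 2 libraries can give (SD, n = 2, exact permutation p = 0.333). This difference was 0.680 points with stricter limits and 1.77 points at equal depth. Against other peaks, values follow in the order normal growth 1 and 2, cold shock 1 and 2. Odds ratios of the chromosome's minus strand were 0.855, 1.18, 1.17 and 0.928 (two-sided Fisher's exact tests, adjusted p = 0.0242, 0.00678, 0.0142 and 0.316). These lay on opposite sides of 1 within each condition. Odds ratios of the second replicon's plus strand were 1.75, 1.61, 1.88 and 1.69 (two-sided Fisher's exact tests, adjusted p = 0.0146, 0.0154, 0.0142 and 0.0569).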

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

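All tests in this part were chosen after the patterns they bear on were seen. What those on depth and on reads outside the loci would show was set down before they were run. At 5 regions the fold over input was above 1 in every library of normal growth and below 1 in every library of cold shock, and the difference between the conditions was not tested. All 5 lay in the 4 loci of depleted peaks. The deposited log2 fold was lower in cold shock by the differences −3.06 at 1537489 to 1537558 on the plus strand and −2.99 at 1891748 to 1891820 on the minus strand, which mirror each other. The other differences, all on the minus strand, were −0.43 at 1310960 to 1311064, −0.70 at 1765854 to 1765958 and −0.37 at 1892461 to 1892497. Such regions numbered 2 when libraries were paired by replicate number and 9 when normal growth replicate 1 was paired with cold shock replicate 2, so the count alone does not speak of condition.

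The first pattern is the fall of the fold at 18 regions with more input reads in cold shock, the first 2 of those above among them. Choosing these regions by their input largely fixes that fall. A loss of eCLIP reads was looked for at the 74 regions chosen by a fold over 2-fold lower in both cold shock libraries, whatever their input. Their median eCLIP change was −0.288 on the log2 scale (quartiles −0.85 and 0.05), where that of the fold was −2.30, although eCLIP fell more than input rose at 12 of them. The fall lay mostly with input there, but choosing by fold also picks regions whose input rose by counting error. Of the 74, 17 are among the 18 regions, so the cause is not decided. Grouping normal growth replicate 1 with cold shock replicate 2 gave 93 regions with a fold over 2-fold lower in the remaining libraries. Scaling of the inputs would move all regions alike. The median input change was 0.0570 at the 66 regions in the loci (quartiles −0.30 and 0.28), but these cannot decide. They hold nearly all peaks with at least 1000 input RPM, so scaling to the library total keeps them near level. Over all 1254 regions the median was 0.36 (quartiles −0.14 and 0.86), against 3.28 at the 18, which argues against scaling as the whole cause. The median region holds only 1 or 2 input reads, and the 18 were chosen for their rise, and both limit this. Centring on the median region still lowered the count of regions with more input from 18 to 9. The input change of the 18 then had quartiles of 2.56 and 3.02 on the log2 scale, against 2.92 and 3.38 before. Sharing of reads between paired loci is argued against for the 14 regions that lay more than 350 nt from the 4 loci. More short RNA in the cold shock inputs stays open. Outside the loci the input of short regions rose by 2.34 more on the log2 scale than that of longer ones (19 against 11 regions with at least 5 input reads in each library), but 11 of the 19 are among the 18 regions chosen for their rise, so the test cannot decide. An effect of the cold shock and of the preparation of those inputs on the RNA in them was not tested.

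The second pattern is that normal growth replicate 1 shared more enriched peaks with cold shock replicate 2 than with its own replicate. Depth is argued against only for reads in peaks already called: over 10 thinnings to equal eCLIP and input reads the excess was 4.56 ± 0.25 percentage points (SD over thinnings), against 4.78 as deposited. A different share of reads outside the 4 loci of depleted peaks is argued against in the same limited way, with an excess of 5.01 ± 0.30 points after matching the median eCLIP reads there. That median was 45 and 38 reads in normal growth replicate 1 and cold shock replicate 2, against 27 and 17 in normal growth replicate 2 and cold shock replicate 1. Peaks were not called again in either test, so peaks missed in a library with fewer reads could not appear. An effect on which peaks were called stays open. Among the 1000 strongest peaks the excess was −6.90 points, so the pattern may rest on the weaker peaks. Culture density stays open and was not tested: if the libraries follow the order of the cultures in the labels, these 2 libraries share a density of 1.0 and the others one of 0.8. Library preparation was not tested either.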

How the results depend on the processing

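Stricter and looser limits, the 50% overlap, merged enriched peaks, leaving out each library, the replicate block for class shares and a looser limit for the other condition were chosen before the data were examined, and all others, with leaving out a library for read numbers, after the data were seen. Of 150 values recomputed for 23 results, 105 kept their direction and side of the threshold (odds ratios), their sign (class shares), a size within 1.5 times (counts) or a place in the 95% Wilson interval of the first value (overlaps). The 105 include the class shares under the replicate block and the crossed pairing, which could not differ from the first values. The overlap of normal growth replicates was 51.2% with stricter limits, 27.5% with 50% of both peaks, 52.1% with windows of 100 nt, 63.95% for the strongest 1000 peaks and 50.2% after matching reads outside the loci. That of cold shock replicates was 16.4% with 50% of both peaks, 38.6% with windows and 31.5% for the strongest peaks. At equal depth the odds ratio of the second replicon in cold shock replicate 2 was 0.793. The cause was not tested, except that 50% overlap asks for more. Class shares turned in sign for the second replicon without normal growth replicate 1 (0.0617 points, range −0.666 to 0.0617) and for the minus strand of the chromosome with stricter limits (0.0801 points) and without normal growth replicate 2 (range −1.17 to 0.636), and the cause was not tested.

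Leaving out each library gave 5363 to 6230 regions bound in normal growth, 4438 to 4943 in cold shock, 1266 to 1853 in all libraries, 964 to 2684 in normal growth only and 380 to 2156 in cold shock only, where fewer libraries had to pass. With no peak of the other condition at the looser limit, 571 and 206 regions were bound in 1 condition only. The 18 regions with more input in cold shock became 30 with at least 5 input reads, 65 with no minimum, 9 centred on the median region and 27 to 45 without 1 library. Regions with more eCLIP reads in cold shock numbered 12 centred on the median region, 0 centred on the depleted loci and 3 to 103 without 1 library, and those with fewer numbered 1 centred on the depleted loci and 6 to 127 without 1 library. With 2 libraries per condition the exact permutation test used here cannot give a p below 0.333, and depth limits what a missing peak means.

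Same-numbered replicates did not deviate together over the 1254 regions (correlation −0.255 for eCLIP reads, −0.071 for input reads and −0.070 for the fold). Whether libraries of the same number were prepared together cannot be told from this. With the replicate block the differences were again −0.302, −0.269 and 4.30 points, with exact sign-flip p = 1, 1 and 0.5. The mean of paired differences is the same under any pairing, so these values could not change. Of 3 classes, 0 were called without the block, under it or under the crossed pairing. That was fixed in advance, since the smallest p is 0.333 without a block and 0.5 for sign flips in 2 pairs. Over 2-fold the same way within both pairs, eCLIP reads in cold shock were higher in 3 regions and lower in 13 with the replicate block, and 6 and 17 with the crossed pairing, and input was higher in 21 and 26. A 50% overlap could not change which regions hold a peak, since regions contain whole peaks. Alternatives for gene-level results (protein-coding genes only, logistic model, background, codon window and GC content) were not run, since no annotation of this strain was used here.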

Other observations

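The tests in this part were chosen after the results were seen. The hypothesis that each pair of depleted loci with matching peak ends holds 2 copies of 1 abundant RNA, with reads placed on both copies, was tested by comparing matching peaks. The larger of the median differences in eCLIP reads between matching peaks was 0.0293 on the log2 scale (the mirrored pair, where 31.9% of peaks matched), against 0.337 for peaks of equal length at other offsets of that pair and 0.456 for those of the other pair. At peaks that overlapped after the offset without matching ends, the median difference was 0.0278 (580 peaks) and 0.0446 (79 peaks), so the near-equal reads did not depend on matching ends. The loci of each pair were 2882 and 3044 nt and 1398 and 1398 nt long, and the gene table of the HB8 strain lists 6 rRNA genes, so copies of large rRNA genes are a candidate explanation that was not tested against a genome sequence. Whether Hera contacts this RNA less than other RNA does not follow from the depletion and was not tested.

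The eCLIP libraries differed in how their reads were spread between the depleted loci and the other regions. At 66 regions in the loci the median was 3641, 4993, 4522 and 4202 eCLIP RPM in normal growth replicates 1 and 2 and cold shock replicates 1 and 2. At the 1188 regions elsewhere with a peak in all 4 lists it was 33.4, 17.1, 16.2 and 32.1 in the same order, so normal growth replicate 1 and cold shock replicate 2 had the higher values outside the loci.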
